A study of Mus musculus with 13 samples.

How the data were processed

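Gene expression was measured by RNA sequencing in 10 mouse libraries, and binding of Fezf2, a zinc-finger transcription factor of the developing forebrain, by chromatin immunoprecipitation and sequencing (ChIP-seq) in 3 libraries. Per the labels' protocols, the knockout and wild-type RNA came from whole neocortex of C57BL6/J mice at postnatal day 0, where a floxed Fezf2 allele was removed from progenitors by Cre recombinase under Emx1 control, and was prepared with a TruSeq mRNA kit. The overexpression and GFP libraries came from CD-1 mice electroporated in utero at embryonic day 16.5. The sample titles name the treated samples Fezf2 + GFP and the controls GFP. Cells were sorted by fluorescence at postnatal day 3, and their RNA was amplified with the NuGEN Ovation V2 system. The ChIP-seq libraries came from N2A cells, a mouse neuroblastoma line, fixed 48 h after transfection with V5-tagged Fezf2 or the V5 tag alone, and precipitated with an antibody to V5. Per the labels, reads were single and 75 bp long.

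The authors deposited raw counts per Ensembl gene for the 10 RNA libraries. The submitters' processing notes name FastQC, STAR 2.4.0e, Bowtie 0.12.5, SAMtools, HTSeq 0.6.1, MACS2 2.0.9 and the mm9 build, without tying each tool to a step, and the gene annotation is not given in the sources used here. Strand handling is not given either, so overlapping and antisense genes, and copies with near-identical sequence, may share reads. The authors also deposited RPKM values for the same libraries. For the knockout and wild-type libraries these equalled the counts divided by library total and a length per gene. For the sorted-cell libraries they did not: they were lower than count-based values by a factor that differed by library (median ratio 0.254 to 0.455), and genes with a count of 0 had RPKM above 0, so these RPKM values came from another count than the deposited counts. The peak lists hold, per peak, the pileup signal at the summit, a fold enrichment ratio over the control and −log10 p and q, as MACS2 gave them per the file headers of the Fezf2-E-V5 list. The parameter lines were present only in that list. They give a control library of 25001753 tags, 22510850 Fezf2-E-V5 tags, a q limit of 0.01, a fragment size of 142 bp and a tag size of 105 bp, which differs from the read length of 75 bp in the labels. The Fezf2-A-V5 list had lost its parameter lines and the names of 2 columns, which were taken as −log10 p and q from the column order of the Fezf2-E-V5 list.

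Of 35972 gene identifiers, 31707 (88.1%) had a symbol in the gene name table used, 1883 were named through the symbol in the count table and 2382 kept that symbol. Sorted cells were analysed with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood F test, Benjamini-Hochberg adjustment, limit 0.05) in R 4.3.3, over the 5 Fezf2 overexpression and 3 GFP libraries alone. TMM-scaled CPM and log2 fold changes were computed here from the deposited counts. Each SE of a log2 fold change was back-calculated, as its absolute value divided by the square root of the F statistic. The filter left 13754 genes. All 34 gene lists were fixed before the data were examined, as were the groups, the main tests and most alternatives. They hold markers of projection neuron classes, other neurons, glia, progenitors and vessels, genes of axon guidance, adhesion, channels, the cell cycle and stress responses, and ribosomal, mitochondrial and sex-linked genes. The results of 1 of these lists, which stays in the counts of lists, and of some genes are not reported here. Lists with at least 5 tested genes were compared with the other genes by camera (limma 3.58.1) at a preset correlation of 0.01, and again with a correlation estimated per list and by fry, which asks whether a list's genes move one way without comparing them with others. The matching of list members was corrected after list results had been seen: it had at first counted retired identifiers of Cux2, Pou3f1 and Efna5 as extra members. That matching is kept as an alternative and called 10 lists where the corrected one called 7.

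For the knockout and wild-type libraries, of which there was 1 each, log2 ratios of TMM-scaled CPM with a prior count of 2 were taken for genes with at least 5 CPM in either library. Their 95% intervals are exact binomial intervals. They cover counting error only, since reads are not independent molecules, and say nothing of differences between animals. The median of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Random lists draw genes independently, whereas genes of one list can move together from library to library. The percentiles therefore describe this pair of libraries and are not p-values. The Fezf2-A-V5 and Fezf2-E-V5 peak lists were intersected with bedtools 2.31.1 at a minimum of 1 bp and compared with 100 shuffles within chromosomes. Peaks are given in mm9 coordinates. They were not assigned to genes, because the annotation at hand is for GRCm38. The comparison of peaks with called genes was therefore not run.

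Named genes followed a rule set in advance. In overexpression these are Fezf2, Rnd3 and Arhgap35, then, because fewer than 10 genes passed, the 10 genes of smallest p in each direction, and up to 4 members per list that passed when adjusted over the list alone. Further list members quoted as examples were chosen after their values were seen. In the knockout comparison the rule took the same 3 genes, the 10 largest log2 ratios each way and the 3 largest absolute ratios of each list outside the central 95% of random lists. Unnamed gene models, pseudogenes, mitochondrial and sex-linked genes were left out of it.

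Library totals were 3245932 to 5801839 counts in sorted cells, 17856211 in the library labelled knockout and 11818437 in wild type. In data simulated from the 13754 genes of the sorted-cell libraries, with 200 genes changed in each of 5 runs, the edgeR test recovered 36% of 2-fold and 80.8% of 4-fold changes, and 3.6% of its calls were false. The simulation drew genes independently and changed many more genes than were called in the real data. Recovery may be lower, and the false share higher, in the real libraries. No pair of libraries agreed within sampling noise (the lowest chi-square per degree of freedom was 5.81), so each was counted as a separate sample. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Alternatives covered RLE and upper-quartile factors, low-count filters, a limit of 0.01, DESeq2 1.42.0, limma on log2(RPKM + 1) and log2(RPKM + 0.1), each library left out, the shared replicate numbers as a block, and other floors, priors, scalings and overlaps. After seeing the data, sex as a term, voom with quality weights, libraries with low correlation left out together, mitochondrial ribosomal RNA left out, protein-coding genes alone, sets at an unadjusted p under 0.05 and an RPKM filter were added. Figures and tables were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.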

Results

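The series addresses which genes Fezf2 regulates in the developing mouse neocortex. Its samples comprise 5 libraries of sorted cells that received Fezf2 and GFP by their titles, and 3 of sorted cells that received GFP. There were also 1 neocortex library labelled Fezf2 knockout and 1 wild-type neocortex library. ChIP-seq covered N2A cells with the constructs named Fezf2-A-V5 and Fezf2-E-V5 and a V5 control. How constructs A and E differ is not given in the sources used here. Total counts were 3777983, 3759942, 4221823, 3484539 and 3777281 in Fezf2 replicates 1 to 5 and 5801839, 3986451 and 3245932 in GFP replicates 1 to 3. Mitochondrial ribosomal RNA took 20.2% to 26.0% of the counts in sorted cells and 0% in the library labelled knockout and the wild-type library. All mitochondrially encoded genes together took 21.0% to 27.1% in sorted cells and also 0% in both neocortex libraries. The absence there is thus not of ribosomal RNA alone, and its cause was not tested. Fezf2 replicate 5 and GFP replicate 1 had Xist at 5227 and 5032 CPM and next to no Y-linked counts, as female animals do, while the other sorted-cell libraries had Xist at 15.9 to 25.3 CPM.

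The first comparison asked which genes changed in cells given Fezf2. Fezf2 itself rose from 8.07 ± 4.28 CPM (SD, n = 3) to 124 ± 28.7 CPM (SD, n = 5), a log2 fold change of 3.91 (SE 0.33, edgeR adjusted p = 6.27e-05). Its level was 142, 138, 85.1, 151 and 101 CPM in the Fezf2 libraries and 8.62, 12 and 3.54 CPM in the GFP libraries, and the count does not separate plasmid from endogenous transcript. Eif1b, which encodes a factor of the translation initiation machinery, fell by 1.20 on the log2 scale (SE 0.18, edgeR adjusted p = 0.0458), from 358 ± 14.1 to 155 ± 37.1 CPM, and each of the 5 Fezf2 libraries lay below each of the 3 GFP libraries. Eif1b is close in sequence to Eif1, so its count is uncertain. Of 13754 genes tested, these were the 2 that passed, 1 higher and 1 lower.

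Rnd3 and Arhgap35, named whatever their values, did not pass. Rnd3 stood at 54.2 ± 17.4 CPM with Fezf2 and 27.3 ± 7.57 with GFP, a log2 fold change of 1.0 (SE 0.30, edgeR adjusted p = 0.719), and Fezf2 replicate 1, at 25.9 CPM, lay within the range of the GFP libraries. Arhgap35 had a log2 fold change of 0.00 (SE 0.13, edgeR adjusted p = 0.997), at 687 ± 31.6 against 686 ± 26.2 CPM.

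**Figure D1:**
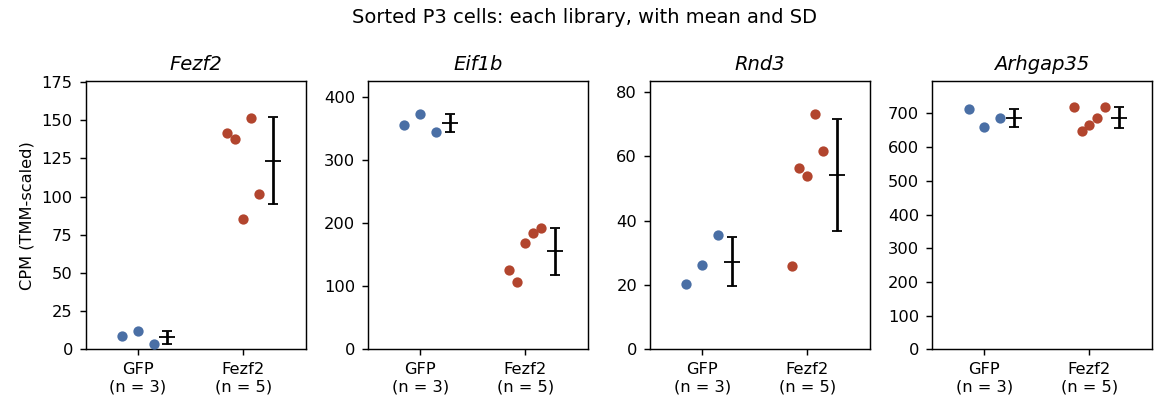
TMM-scaled CPM (vertical axes, linear, from 0) of Fezf2, Eif1b, Rnd3 and Arhgap35 in each sorted-cell library, with the mean and SD of 5 Fezf2 and 3 GFP libraries. Fezf2 and Eif1b separate the groups fully, Rnd3 overlaps in 1 Fezf2 library, and Arhgap35 has nearly equal means of 687 and 686 CPM.

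The other genes of smallest p did not pass either, at edgeR adjusted p of 0.31 to 0.719. Among those with higher means in Fezf2 cells were Nwd1 (107 against 43.9 CPM, log2 fold change 1.29, SE 0.24), Syne1, which links the nuclear envelope to the cytoskeleton (67.0 against 34.8 CPM), the condensin subunit Ncaph (24.4 against 8.78 CPM), Zeb1, a transcriptional repressor of progenitors (262 against 161 CPM), and the transmembrane semaphorin Sema6d (196 against 104 CPM). Zfp14, a zinc-finger gene, had 11.8 against 2.06 CPM. S1pr3, a receptor of sphingosine-1-phosphate, had 17.3 against 6.50 CPM, Pla2g7, which breaks down platelet-activating factor, had 50.8 against 19.3 CPM, and the proteoglycan core gene Srgn was near the detection limit at 3.34 against 0.08 CPM. Among those with lower means were Pou3f3, a POU-domain factor of upper-layer neurons (216 against 348.0 CPM, log2 fold change −0.69, SE 0.15), the small nucleolar RNA host gene Snhg5 (68.2 against 123 CPM), the cold-induced RNA-binding protein gene Cirbp (70.4 against 115 CPM), Id2, an inhibitor of basic helix-loop-helix factors (62.9 against 106 CPM), and Hs6st2, which sulfates heparan sulfate (137 against 241 CPM). Ip6k2, Sh3bp5, Fam19a2 and Nudt11 had log2 fold changes of −0.66, −0.59, −1.14 and −0.90.

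At an unadjusted p under 0.05, edgeR gave 901 genes (593 higher, 308 lower), against 688 that chance alone would give. The groups did not overlap for 648 genes, 4.7% of those tested, where chance gives 3.6%. The coefficient of variation between samples of a group, beyond counting error, was 29.8%. The call for Fezf2 held without each library in turn, whereas that for Eif1b held only without Fezf2 replicate 4 and was lost without any other single library (edgeR adjusted p 0.0532 to 0.618), so that 1 gene was left in those fits. DESeq2 called 6 genes, adding Nwd1, Syne1, Snhg5 and Pou3f3 to Fezf2 and Eif1b. With no low-count filter edgeR called 117 genes (79 higher, 38 lower), Rnd3 among them (edgeR adjusted p = 0.0192). In that fit the log2 fold changes of Fezf2, Eif1b and Rnd3 were 3.89, −1.215 and 0.988, close to those of the main fit. Their edgeR adjusted p still fell, to 1.05e-48 for Fezf2 and 6.58e-09 for Eif1b. For these genes the smaller p came without a larger change, so the Rnd3 call there rests on the filter.

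Gene lists asked whether whole cell types or pathways moved. Astrocyte, oligodendrocyte lineage, radial glia and cell cycle genes rose as lists on average over the Fezf2 libraries, while ribosomal protein, mitochondrially encoded and cortical glutamatergic identity genes fell. Of 31 lists tested, 7 passed camera at its preset correlation, 4 higher and 3 lower. None of the 7 passed with an estimated correlation (smallest adjusted p 0.4) or by fry (smallest adjusted p 0.159). The estimated correlations were 0.827, 0.752, 0.736, 0.632 and 0.59 for the astrocyte, radial glia, mitochondrial, oligodendrocyte and cell cycle lists. They were 0.09 and 0.036 for the ribosomal and glutamatergic identity lists. All lay above the preset of 0.01, so the camera p-values at the preset overstate the evidence, most of all for the first 5 lists. Of their members, 2 passed when adjusted over the list alone, and none passed over all genes.

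Astrocyte genes rose with a median log2 fold change of 0.82, and 13 of 13 were higher (camera adjusted p = 0.00315; adjusted p = 0.806 with an estimated correlation). The glutamate transporter gene Slc1a2 had 1136 ± 668 against 462 ± 79.8 CPM, the gap junction gene Gja1 50.3 ± 39.6 against 21.2 ± 10.2 CPM, and Mlc1, of astrocyte end-feet, 69.3 ± 39.9 against 35.1 ± 10.4 CPM. The SDs reflect an uneven shift: the astrocyte median relative to the GFP mean was 0.96, 1.54 and 1.12 in Fezf2 replicates 2, 4 and 5, and −0.51 and 0.06 in replicates 1 and 3. Without Fezf2 replicate 4 the astrocyte median was 0.52 and the call was lost (camera adjusted p = 0.054). Oligodendrocyte lineage genes rose by a median of 0.53, with 11 of 12 higher (camera adjusted p = 0.000208; adjusted p = 0.806 with an estimated correlation). They included Bcas1 of early myelinating cells, at a log2 fold change of 1.09 (SE 0.35), the transcription factor gene Sox8 at 0.73 (SE 0.27), and Gpr17, a receptor of oligodendrocyte precursors, at 0.72 (SE 0.28). The oligodendrocyte medians were 0.38, 1.09 and 0.63 in Fezf2 replicates 2, 4 and 5 and 0.19 and 0.01 in replicates 1 and 3. Without Fezf2 replicate 4 the oligodendrocyte median was 0.31 and the list still passed (camera adjusted p = 0.00502), and without Fezf2 replicates 1, 2 and 4, those of lowest correlation with the other libraries, it was 0.33 and did not pass (camera adjusted p = 0.103).

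Cell cycle genes rose by a median of 0.45, with 19 of 22 higher (camera adjusted p = 0.00315; adjusted p = 0.806 with an estimated correlation). Top2a, a DNA topoisomerase of dividing cells, and the proliferation marker gene Mki67 passed when adjusted over the list alone (edgeR, adjusted p = 0.0365 for each), with log2 fold changes of 0.89 (SE 0.26) and 0.93 (SE 0.27). The cell cycle medians were 0.78, 0.87 and 0.71 in Fezf2 replicates 2, 4 and 5 but −0.38 and −0.13 in replicates 1 and 3, and the list call was lost without Fezf2 replicate 4 (median 0.30, camera adjusted p = 0.186). Radial glia genes, of the neural stem cells whose fibers span the cortical wall, rose by a median of 0.45, with 13 of 14 higher (camera adjusted p = 0.0418; adjusted p = 0.838 with an estimated correlation). The matrix gene Tnc stood at a log2 fold change of 0.65 (SE 0.21), Notch1 at 0.60 (SE 0.22) and the glutamate transporter gene Slc1a3 at 0.86 (SE 0.37). The members that moved least were Pax6 at 0.07 (SE 0.28), Hes5 at 0.17 (SE 0.41), Sox2 at 0.20 (SE 0.37) and Vim at 0.22 (SE 0.26). Hopx, the member that was lower, stood at −0.26 (SE 0.58). The radial glia medians were 0.19, 1.01 and 0.62 in Fezf2 replicates 2, 4 and 5 and −0.45 and −0.12 in replicates 1 and 3. The radial glia call was lost without Fezf2 replicate 2, 4 or 5 or GFP replicate 2, at medians of 0.45, 0.25, 0.39 and 0.32 and camera adjusted p of 0.0527, 0.455, 0.185 and 0.18, and without Fezf2 replicates 1, 2 and 4 together (median 0.32, camera adjusted p = 0.103). Without Fezf2 replicates 4 and 5 together, the astrocyte, oligodendrocyte, cell cycle and radial glia lists all lost their call, at medians of 0.31, 0.17, 0.18 and 0.02 and camera adjusted p of 0.718, 0.377, 0.908 and 0.718.

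**Figure D2:**
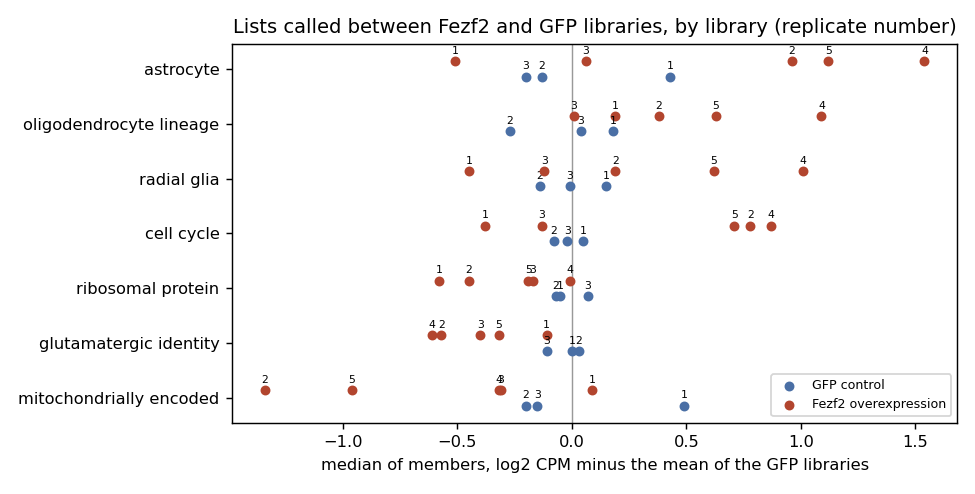
Median log2 CPM of gene lists in each sorted-cell library, relative to the mean of the GFP libraries (log2 axis), with 5 Fezf2 and 3 GFP libraries as points. Astrocyte medians lie at 0.96 or above in Fezf2 replicates 2, 4 and 5, and at −0.51 and 0.06 in Fezf2 replicates 1 and 3.

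Ribosomal protein genes fell by a median of 0.24 on the log2 scale, with 48 of 60 lower (camera adjusted p = 4.43e-05; adjusted p = 0.578 with an estimated correlation). Rpl5 and Rps15a, of the large and the small subunit, had log2 fold changes of −0.70 (SE 0.25) and −0.43 (SE 0.14), and because such genes have many processed copies their counts are uncertain. The ribosomal medians were −0.58, −0.45 and −0.01 in Fezf2 replicates 1, 2 and 4, which had mean correlations with the other libraries of 0.904, 0.913 and 0.912, and −0.17 and −0.19 in replicates 3 and 5, both at 0.932. Genes of cortical glutamatergic identity fell by a median of 0.34, with 11 of 12 lower (camera adjusted p = 0.000701; adjusted p = 0.4 with an estimated correlation). The basic helix-loop-helix genes Neurod2 and Neurod6 stood at log2 fold changes of −0.69 (SE 0.21) and −0.38 (SE 0.17). The glutamatergic identity medians were −0.11, −0.57, −0.40, −0.61 and −0.32 in Fezf2 replicates 1 to 5. Both lists passed camera in each of the 8 fits that left out 1 library. Mitochondrially encoded genes fell by a median of 0.67, with 15 of 21 lower (camera adjusted p = 0.000208; adjusted p = 0.806 with an estimated correlation). Its lower members were mostly transfer RNA genes of low count such as mt-Tt (6.84 against 17.8 CPM), with the respiratory chain gene mt-Nd2 at −0.75 (SE 0.24), whereas mt-Co1, mt-Cytb and mt-Nd1 had log2 fold changes of 0.08, 0.10 and 0.01. The mitochondrial medians were −1.34 and −0.96 in Fezf2 replicates 2 and 5, against 0.09, −0.31 and −0.32 in replicates 1, 3 and 4. The mitochondrial call was lost without GFP replicate 1 (median −0.40, camera adjusted p = 0.0768), and without Fezf2 replicate 2 the median was −0.41 and the list still passed.

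Lists of the neurons that Fezf2 is best known to act in did not pass. Subcerebral projection neuron genes had a median of 0.10 (8 of 10 higher, camera adjusted p = 0.64), with Bcl11b, a factor of corticospinal neurons, at 0.56 (SE 0.25) and Ldb2 at 0.52 (SE 0.23). The largest change in that list was downward, in Crym at −1.15 (SE 0.90), a gene of low count (1.46 against 3.27 CPM). Pcp4, Cdh13, Ntng1 and Nfe2l3, counted as higher, stood at 0.01, 0.03, 0.10 and 0.10. Corticothalamic genes had a median of −0.13 (camera adjusted p = 0.43), callosal and upper-layer genes −0.19 (camera adjusted p = 0.054), genes of glutamate synapses and ion channels tied to the vesicular transporter Vglut1 0.25 (camera adjusted p = 0.0535), interneuron genes 0.49 (camera adjusted p = 0.12), Cajal-Retzius genes 0.59 (camera adjusted p = 0.0535), and subplate genes 0.50 (camera adjusted p = 0.192). When adjusted over the list alone by edgeR, 1 gene passed in each of 4 lists that did not pass as a whole: Pou3f3 among callosal genes, Grm3, a metabotropic glutamate receptor gene, among Vglut1 genes (log2 fold change 0.73, SE 0.19), the interneuron factor gene Dlx1 (0.74, SE 0.20) and the pericyte gene Rgs5 (1.28, SE 0.38).

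Axon guidance receptor genes had a median of 0.11 (17 of 30 higher, camera adjusted p = 0.64), guidance ligands 0.03 (camera adjusted p = 0.787) and cadherins and contactins 0.03 (camera adjusted p = 0.773). Single members stood at log2 fold changes of 0.65 (SE 0.19) for the plexin gene Plxnb1, −0.92 (SE 0.32) for the ephrin receptor gene Epha3 and −1.17 (SE 0.34) for Cdh12, and none passed over the list alone. Microglia genes had a median of 0.41, extracellular matrix genes 0.37, endothelial and pericyte genes 0.61, striatal projection neuron genes 0.08 and potassium channels 0.09, at camera adjusted p of 0.0627, 0.143, 0.146, 0.64 and 0.64. Integrated stress response, p53, heat shock, interferon and immediate early genes had medians of 0.28, 0.13, 0.01, 0.38 and 0.25, at camera adjusted p of 0.402, 0.666, 0.787, 0.787 and 0.773. Synapse, intermediate progenitor and sex-linked genes had medians of −0.01, −0.01 and −0.10, at camera adjusted p of 0.805, 0.961 and 0.805. For these last 3 lists the test pointed upward against a median below 0, and the mean of the sex-linked list, −0.16, also lay below 0. Red blood cell, meningeal and choroid plexus genes had 2, 4 and 3 members tested, too few for a test.

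Loss of Fezf2 was compared in the neocortex at birth, with 1 library on each side and so no test. Percentiles among random lists make no allowance for genes of a list that move together, and so overstate how unusual a list is. Fezf2 was not lower in the library labelled Fezf2 knockout: it had 955 counts there and 607 in wild type, or 53.8 and 51.8 CPM, a log2 ratio of 0.05 (95% interval −0.09 to 0.20). A count over the whole gene cannot show a partial deletion, and which part is floxed is not given in the sources used here, so the genotype was not checked by this value and directions below rest on the label. Both libraries were from male animals by their Xist and Y-linked counts.

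Corticothalamic genes, and most subcerebral projection neuron genes, were lower in the library labelled Fezf2 knockout. The median log2 ratio of corticothalamic genes was −0.82, lower than each of 10000 random lists (percentile 0), and 14 of 14 members were below 0. Among them were Foxp2, a forkhead factor gene of layer 6 (−2.05, 8.74 against 36.6 CPM), the corepressor gene Tle4 (−1.94, 35.5 against 137 CPM) and the heparan sulfate sulfotransferase gene Hs3st4 (−1.85). Subcerebral projection neuron genes had a median of −0.43 (percentile 0.06), with 8 of 13 members below 0 and 5 above. They included Tcerg1l at −1.86, Nfe2l3 at −1.49, Crym, a thyroid hormone-binding protein gene that is also on the corticothalamic list, at −1.35, and Bcl11b at −1.14, while Sulf1 and S100a10 stood at 1.25 and 1.01. Striatal projection neuron genes had a median of −0.52 (percentile 0.1), with Ppp1r1b, a phosphatase regulator also on the corticothalamic list, at −1.60, the dopamine receptor gene Drd1 at −1.37 and Meis2 at −0.79. Glutamatergic identity genes had a median of −0.25 (percentile 1.33), with Neurod1 at −0.89 and Neurod6 at −0.85, but Emx1, whose regulatory sequence drives the Cre, at 1.04. Callosal and upper-layer genes stood at a median of −0.02 (percentile 38.4) and a mean of 0.08.

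Radial glia genes had a median of −0.37 (percentile 0.07), with Hes1 and Hes5, targets of Notch signalling, at −0.63 and −0.47, the latter with an interval that included 0, and Notch1 at 0.59. Cadherins and contactins had a median of −0.18 (percentile 0.49), with Cdh7, Cdh11 and Cntnap5a at −1.27, −1.01 and −0.97. Guidance receptors had a median of 0.17 (percentile 99.2) with members on both sides, such as the Eph receptor genes Ephb6 at 0.65 and Ephb1 at −0.80 and the plexin gene Plxnb2 at 0.61. Rnd3 stood at −0.48 (95% interval −0.62 to −0.35, 53.7 against 75.2 CPM) and Arhgap35 at 0.01 (95% interval −0.03 to 0.06).

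On the other side, immediate early genes, which respond to activity and to tissue handling, had a median of 1.11 and endothelial and pericyte genes one of 0.48, both above each of the 10000 random lists. Egr1 stood at 1.85, the AP-1 genes Fosl2 and Junb at 1.57 each, and the vessel genes Slc2a1, Igfbp7 and Vtn at 1.19, 0.91 and 0.75. Ribosomal protein genes had a median of 0.15 (percentile 99.8), with Rpl3, Rpl29 and Rpl26 at 2.04, 1.42 and 1.15, all uncertain because of their processed copies. The p53 genes had a median of 0.34 (percentile 99.5), with the stress gene Sesn2 at 1.29, the cell cycle inhibitor gene Cdkn1a at 0.92 and Gtse1 at 0.75.

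**Figure D3:**
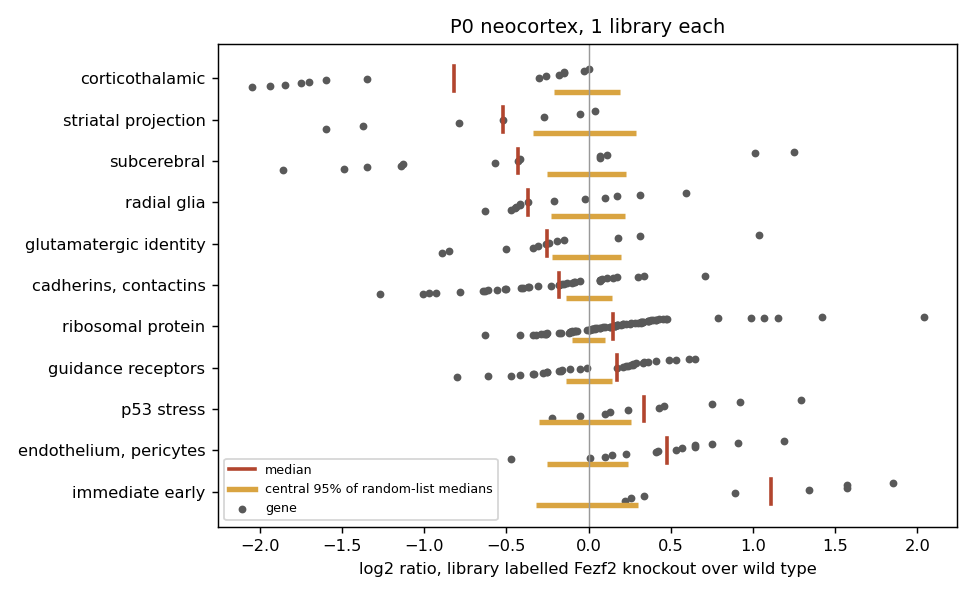
Log2 ratio of the library labelled Fezf2 knockout over wild type (horizontal axis) for each measured gene of the 11 lists outside the central 95% of random lists, with the list median as a vertical mark and that central range as a bar. Medians run from −0.82 for corticothalamic genes to 1.11 for immediate early genes.

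In all, 110 of 11218 genes were at least 2-fold higher and 151 at least 2-fold lower, and the median ratio over all genes was 0.004. The lowest named genes were Myo7a, a myosin of sensory hair cells (−5.76, 19 against 763 counts), the tubulin gene Tuba1c (−4.62), Ndufs5 (−3.93), the neurexophilin gene Nxph3 (−3.09), the cystine transporter gene Slc7a11 (−2.49), the serotonin receptor gene Htr2a (−2.25), Fign (−2.08), Foxp2, Scoc (−2.04) and Tle4. The highest were Hddc3 (2.81), the growth factor gene Vegfd (2.57), the neuropeptide gene Cck (2.38, 133 against 25.4 CPM), Matn2 (2.33), the potassium channel gene Kcnn1 (2.32), Rpl3, the NF-kB subunit gene Relb (1.91), Dctd (1.88), Egr1 and the glutamate receptor gene Grin2a (1.75). Tuba1c, Ndufs5 and Rpl3 have near-identical copies and are uncertain. At a floor of 20 CPM, 49 genes were at least 2-fold higher and 63 lower. Of the 26 lists measured, 11 lay outside the central 95% of random lists, and the striatal, radial glia, glutamatergic identity, guidance receptor and p53 lists came inside under 1 of 5 alternatives, the floor of 20 CPM, at medians of −0.27, −0.21, −0.21, 0.08 and 0.13 (percentiles 8.3, 4.8, 3.3, 82.7 and 74.3). The immediate early median was 0.62 at that floor, still above the random lists.

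A further comparison asked whether the genes that changed with Fezf2 gain also differed with its loss. Eif1b, lower with Fezf2 overexpression, had a log2 ratio of −0.26 in the library labelled Fezf2 knockout (percentile 18.0 among random genes), and Fezf2 itself stood at 0.05 (percentile 55.5). With 1 gene on each side these values describe single genes. Fezf2 is the gene added in the first experiment and floxed in the second, so its value says nothing of genes that respond to it. Across the 10867 genes measured in both experiments, the log2 fold change of overexpression and the log2 ratio of the library labelled Fezf2 knockout had a Pearson r of 0.011, and genes are not independent replicates.

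Binding was compared between the Fezf2-A-V5 and Fezf2-E-V5 constructs in N2A cells, with 1 peak list each and no replicate check. The lists overlapped far above shuffled positions: 11139 of 18216 Fezf2-A-V5 peaks (61.1%, exact 95% interval 60.4 to 61.9) and 11315 of 21338 Fezf2-E-V5 peaks (53%, exact 95% interval 52.4 to 53.7) lay on a peak of the other list. The intervals treat peaks as independent and say nothing of differences between experiments. Shuffling gave a mean of 98.9 shared Fezf2-A-V5 peaks (0.54%, at most 119 in 100 shuffles). Shuffled peaks could fall anywhere within a chromosome, so they make no allowance for regions that any ChIP of these cells may favor. Sharing followed peak strength: 88.9% of the strongest 10% of Fezf2-A-V5 peaks by the authors' fold enrichment were shared and 49.1% of the weakest 10%, against 80.4% and 43.9% for Fezf2-E-V5. Fezf2-A-V5 peaks had a median width of 281 bp and a median fold enrichment of 7.51, and Fezf2-E-V5 peaks 232 bp and 6.70.

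The peak of highest fold enrichment in both lists lay on chromosome 5, at 123220850 to 123221506 (mm9), with a fold enrichment of 55.7 in the Fezf2-A-V5 list and 46.6 in the Fezf2-E-V5 list, and summits 22 bp apart. The next shared peaks by Fezf2-A-V5 enrichment lay on chromosome 15 at 62734592 to 62735046 (38.0), chromosome 16 at 22816403 to 22817438 (35.1), chromosome 9 at 60660831 to 60661636 (34.1) and chromosome 7 at 148111746 to 148112238 (32.9), where the Fezf2-E-V5 peaks had fold enrichments of 20.1, 20.1, 24.1 and 27.0. Genes at these positions were not looked up, for want of an mm9 annotation. The Fezf2-E-V5 header names the V5 control, and if the Fezf2-A-V5 list used it too, part of the overlap may come from the shared control. With a reciprocal overlap of at least 50%, 45.2% of Fezf2-A-V5 and 38.6% of Fezf2-E-V5 peaks were shared.

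**Figure D4:**
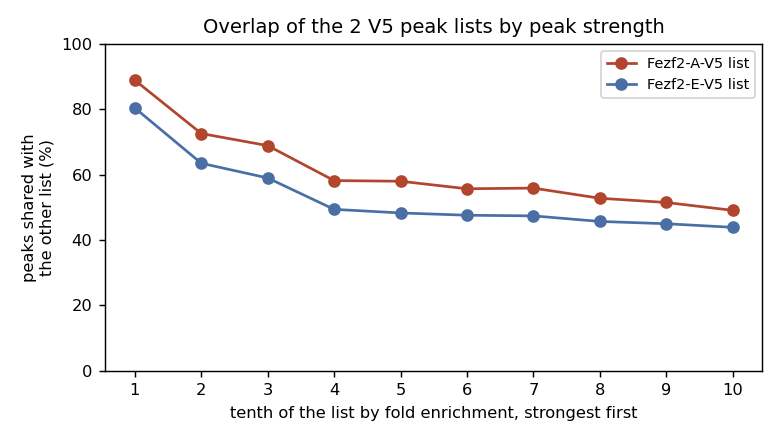
Percent of peaks shared with the other list (vertical axis, from 0) in 10 parts of equal size of each list, strongest fold enrichment on the left. Sharing runs from 88.9% to 49.1% for Fezf2-A-V5 and from 80.4% to 43.9% for Fezf2-E-V5.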

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

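The tests of sample mixture, swapped labels, a remaining transcript and near-identical copies were chosen only after the results they bear on had been seen, and that of mixture replaced a correlation across libraries whose values had been seen; those of sex, gene length and other splits of the samples were written before.

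Of 60 values screened within the 5 Fezf2 overexpression libraries, 7 had 1 library far from the others, where about 1 in 20, or 3 of 60, would by chance. The log2 CPM of Pou3f3 was 7.32 in Fezf2 replicate 2 (nearest other 7.75), and that of Ip6k2 was 5.91 there (nearest other 6.27). The subcerebral list median was −0.40 in Fezf2 replicate 1 (nearest other 0.14), and the p53 list median was −0.48 there (nearest other 0.20). In Fezf2 replicate 4 the Vglut1 list median was −0.24 (nearest other 0.22) and the integrated stress response median 0.53 (nearest other 0.14). Xist stood at 5227 CPM in Fezf2 replicate 5 (nearest other 22.1), the female library of that group.

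Astrocyte, oligodendrocyte, radial glia and cell cycle lists were higher, and the ribosomal protein list lower, on average over the Fezf2 libraries. Chance was not excluded: of the 56 splits of the 8 libraries into 5 and 3, 22 called at least 7 lists (highest other 13) and 3 called at least 2 genes (highest other 182, with Fezf2 replicates 2, 4 and 5 apart from the rest, which points to a structure of the samples). The tables argue against sex, since with it as a term the median of the 4 list medians was 1.08 times its value without it. Gene length was not excluded for the ribosomal protein list. Across genes, log2 fold change rose weakly with length (Spearman rho 0.126). Random lists matched on length and expression centered on a median of −0.03, against −0.24 for ribosomal protein genes (percentile 0.02). The match used a single length per gene, which need not be that of the transcripts present. Its random lists also draw genes independently, so the percentile does not settle the matter. An effect of Fezf2 on glia that differs between samples, and different mixtures of cells in the sorted samples, both stay open. Either may place the 3 highest libraries of the oligodendrocyte, radial glia and cell cycle lists (3 of 3) where those of the astrocyte list were, in Fezf2 replicates 2, 4 and 5, a near tie for radial glia (0.19 against 0.15). A sort by fluorescence would remove cells without a plasmid, yet the astrocyte gene Slc1a2 had 462 ± 79.8 CPM in GFP cells. That level does not tell whether its cells carried a plasmid. All 13 of 13 tested astrocyte genes, 0 of them on another list, had 1 CPM or more there. This count adds little, since the low-count filter had already removed genes of low count.

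Fezf2 stood at the same level in the library labelled Fezf2 knockout and in wild type. Swapped labels predict a high median of the subcerebral list, known to lie downstream of Fezf2, in the library labelled knockout. Its median lay on the low side (percentile 0.06), with 8 of 13 members lower and 5 higher. With 1 library on each side this does not decide the matter. Striatal projection neuron genes were also low (median −0.52, percentile 0.1), and a difference in dissection was not tested. A transcript made from the part of the locus that recombination leaves could not be told apart from an intact gene, since the log2 ratio of 0.05 covers the whole gene. Cells outside the Emx1 lineage were not tested as a source.

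The most extreme log2 ratios between the library labelled Fezf2 knockout and wild type may come from reads shared between near-identical copies: 9 of the 13 genes past 8-fold were pseudogenes or unnamed gene models, against 424 of 11205 other genes (odds ratio 57.2, Fisher exact two-sided p = 1.09e-10). The lower corticothalamic genes Foxp2, Tle4 and Hs3st4 were not among the 13. A strain difference between the litters was not tested.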

How the results depend on the processing

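Sex as a term, voom weights, libraries with low correlation left out, mitochondrial ribosomal RNA left out, replicate numbers 1 to 3 without the block, retired identifiers, the RPKM filter, the unadjusted sets and protein-coding genes alone were chosen after seeing the data. The call for Fezf2 held in 23 of 23 alternatives (log2 fold change 3.23 to 4.27, adjusted p up to 0.00353) and that for Eif1b in 10 of 23 (−1.45 to −0.99, adjusted p up to 0.975). Rnd3 passed in 1 of 23 (adjusted p = 0.0192 with no low-count filter, range to 0.999). Its log2 fold change was 0.988 in that fit and 0.998 in the main fit. Against 2 called genes, no low-count filter gave 117 (79 higher, 38 lower), DESeq2 6 (adjusted p given for 5801 genes), voom weights 4, Fezf2 replicates 1, 2 and 4 left out 6, and the CPM filter, a limit of 0.01 and sex as a term 1 each; leaving out 1 library gave 1 to 2. Other factors, RPKM and mitochondrial ribosomal RNA left out gave 2, of which those by RPKM shared 1 gene, Fezf2. The cause was not tested, except that the limit of 0.01 is stricter by construction.

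Against 7 called lists, an estimated correlation and fry gave 0 each, voom weights 12 and retired identifiers 10 (adding callosal, Vglut1 and Cajal-Retzius genes at camera adjusted p of 0.0346, 0.0481 and 0.0481); leaving out 1 library gave 6 to 11, the highest without Fezf2 replicate 1. The ribosomal, glutamatergic identity, mitochondrial, oligodendrocyte, astrocyte, cell cycle and radial glia lists were called in 16, 16, 15, 13, 13, 13 and 9 of 18 alternatives. Over 555 list tests under alternatives, 491 kept their side of the limit, 29 lost the call in the same test direction, 33 gained it, and in 2 the test of a called list turned direction. The cause was not tested.

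Numbers 1 to 3 are shared by both groups but did not pair the samples (correlations of deviations −0.053, −0.014 and −0.045, and no GFP library correlated best with its own number). With these numbers as a block, 10 genes (1 higher, 9 lower) and 5 lists were called, against 6 genes and 5 lists in the same libraries without it. In both fits the 3 lower lists kept their call and the 4 higher lists lost it. With the block the astrocyte, oligodendrocyte, cell cycle and radial glia medians were 0.19, 0.18, −0.02 and −0.010 (camera adjusted p 0.624, 0.324, 0.813 and 0.659), and without it 0.31, 0.17, 0.18 and 0.021 (0.718, 0.377, 0.908 and 0.718); the radial glia test turned downward in both. Fezf2 replicates 4 and 5 were absent from these fits.

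The ratio in the library labelled Fezf2 knockout of genes called lower was −0.26; it was −0.177 for genes called with the block, −0.109 without Fezf2 replicates 1, 2 and 4, −0.121 with voom weights and −0.045 for unadjusted sets, which hold other genes. Fits that called no gene lower, or none on a list, gave no value. A floor of 20 CPM left 112 genes past 2-fold in place of 261, having fewer genes; total-count scaling gave 261, RPKM 231, a prior count of 5 gave 244 and protein-coding genes alone 227. Of 128 list medians there, 119 stayed within their spread and 9 moved. Shares of Fezf2-A-V5 and Fezf2-E-V5 peaks in common, 61.1% and 53%, were 55.2% and 47.6% in the stricter part of each list, 45.2% and 38.6% with reciprocal overlap, and 54.8% and 46.9% for summits within 200 bp. Reciprocal overlap is stricter by construction. The stricter part dropped weaker peaks from both lists and so removed possible partners. Against the full other list, stronger peaks were shared more often. For summits the cause was not tested. Peaks near called genes, at any distance, were not run. At this depth, spread and number of libraries, 36% of simulated 2-fold changes were recovered, with genes drawn independently and 200 of them changed. The part of depth was not tested.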

Other observations

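The strongest pileups of the peak lists were not their strongest peaks. In the Fezf2-A-V5 list the highest pileup was 704, on chromosome 14 from 13174896 (mm9), at a fold enrichment of 1.67. A neighbouring peak from 13176868 had the same pileup, at a fold enrichment of 1.65. In the Fezf2-E-V5 list the highest pileup was 544, on chromosome 9 from 35112817, at a fold enrichment of 1.26. At such low ratios these pileups stood little above the control, and their source was not tested. The X chromosome held 224 Fezf2-A-V5 and 183 Fezf2-E-V5 peaks, against 1560 and 1796 on chromosome 11.

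The lists of the library labelled Fezf2 knockout not yet described lay inside the central 95% of random lists. Glutamate synapse and ion channel genes tied to Vglut1 had a median of −0.18 (percentile 2.96) and a mean of 0.01, heat shock genes a median of −0.24 (percentile 3.22), interneuron genes −0.17 (percentile 6.02, but −0.25 and percentile 2.3, outside that range, over protein-coding genes alone), intermediate progenitor genes −0.28 (percentile 7.87), and integrated stress response genes 0.22 (percentile 95.5). Astrocyte, oligodendrocyte and cell cycle genes, higher in the Fezf2 overexpression libraries, stood at medians of 0.06, 0.01 and 0.06 there, and the oligodendrocyte median was 0.26 (percentile 95.2) at a floor of 20 CPM.

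A hypothesis written before its test was that gain and loss of Fezf2 move the same genes in opposite directions. The median log2 ratio of the library labelled Fezf2 knockout over wild type was −0.02 for the 483 genes higher in overexpression at an unadjusted p under 0.05, Fezf2 left out (percentile 11.16), and −0.05 for the 263 genes lower (percentile 2.5), so the latter lay on the side opposite to the one predicted. The test does not decide the matter, since 688 of the 901 genes at that p are the number chance gives, and a response of few genes would be diluted; this limit was weighed only after the result was seen. Rnd3 stood at a log2 fold change of 1.0 with overexpression and a log2 ratio of −0.48 in the library labelled Fezf2 knockout, but it was singled out by the study's known interest and did not pass in the first.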
